A study of Homo sapiens with 12 samples.

How the data were processed

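MicroRNAs (miRNAs, short RNAs that silence messenger RNAs) were measured in RNA from exosomes, small vesicles that cells release, of 4 human colorectal cancer cell lines. SW620 and RKO are labelled highly metastatic, HT29 and SW480 weakly metastatic. Each line has 3 arrays, 12 in all, which the series describes as independent experiments. Names of miRNAs are given without the prefix hsa-, and those that differ by a few bases can bind to each other's probes.

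The arrays are 1-colour Agilent human miRNA arrays that carry 2549 human miRNAs, with 5893 probes on 50980 spots, 20 spots for each miRNA. Per the file headers, the deposited scanner files hold intensity values from Agilent Feature Extraction 10.7.1.1, which subtracted the background, removed spatial trends and set detection flags, without normalization between arrays. The authors also deposited a table of log2 values that were quantile normalized between the 12 arrays. Checked on the files, that table ranks the detected miRNAs of each array as the sum of the total signals of their detected probes does, with a Spearman correlation of 1.0, and its lowest value is -3.32. All columns of the table were matched to a scanner file. The scanner files hold other columns too, such as flags, and per the file headers a flag of 1 for a miRNA means that a probe lay above 3 times its error.

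The background-subtracted intensities of the scanner files were the starting point. Spots marked as outliers and controls were left out. The spots of a probe were averaged, then the probes of a miRNA, on the linear scale. Each array was divided by its 75th percentile over the 144 miRNAs detected on all 12 arrays. Values under a floor were raised to it, and log2 was taken. The floor was the median over arrays of the 5th percentile of the scaled signals of detected miRNAs, at log2 -5.67. The 531 miRNAs detected on all 3 arrays of at least 1 line were tested. No spot was saturated, and the number of arrays limits the precision. A miRNA not detected on any array of a line is given as a bound against the lowest detected signal, which was the floor on every array except RKO replicate 3, where it was -5.26. So is one that lay at the floor on most arrays of the lower line. Values at the floor can shrink a fold, and those of RKO replicate 3 can enlarge a fold by which RKO is lower. Each bound holds for this scaling and floor, and can be lower under another.

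Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per line over all 12 arrays, so that the lines share 1 estimate of the spread. The tests are 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested miRNAs within each contrast, with a threshold of 0.05. The contrasts were the mean of SW620 and RKO minus the mean of HT29 and SW480, the 6 pairs of lines, the difference between the SW620 minus SW480 and RKO minus HT29 differences, and the other ways to split the lines into pairs. A miRNA was counted as concordant when it passed in the same direction in all 4 pairs of a highly with a weakly metastatic line. The p-values measure only the spread between arrays of a line. With 2 lines per class, the arrays compare these 4 lines and not metastatic ability as such.

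The miRNAs named were fixed by rule before the data were examined, as were 29 lists of families, genomic clusters and markers of other cell types, the tests and most of the alternatives. The rule takes miR-181a-5p, which the series title names, and up to 12 concordant miRNAs in each direction with the largest smallest difference over the 4 pairs. It adds 3 in each direction that passed for the class contrast without being concordant, and the 5 largest in each direction of every other contrast among those whose arrays do not overlap. Of each list it takes up to 4 members with the largest differences, and lastly the 5 brightest miRNAs. Lists with at least 3 tested members, and the miRNAs numbered 1000 or higher against the rest, were tested with limma's camera with a preset correlation of 0.01. The camera test was repeated with an estimated correlation, and fry was run as well.

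The arrays lie on 2 slides. Slide 1 holds the SW620 and RKO arrays with HT29 replicates 1 and 2, and slide 2 holds HT29 replicate 3 with the SW480 arrays. Values within a slide are given where it holds both groups, without counts where a group has 1 array there. Values with the slide as a block are given too. HT29 alone lies on both slides, so HT29 replicate 3 against HT29 replicates 1 and 2 sets the slide term of that fit. Replicate numbers do not pair the arrays: 4 of 18 pairs of arrays with the same number had residuals correlated above 0.1, and the median correlation was 0.0056 against 0.037 for other pairs. The alternatives were other scalings, the authors' table, other backgrounds, floors, filters and summaries of probes, blocks for slide and replicate, class models, a minimum fold of 2, and leaving out each array. A planned scaling by the percentile over all human miRNAs gave 136 miRNAs for the classes, 44 higher and 92 lower, and 4 concordant. It was set aside after these values were seen, because the percentile was -10.5 on RKO replicate 3, which put 518 of its 531 miRNAs at the floor. On the other arrays it was 1.13 to 9.41, near the background, and scaling by it without RKO replicate 3 was added.

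The procedure was tested on simulated data with the spread of these arrays, in 20 runs with 200 changed miRNAs each. For high against weak lines it found 75.0% of 1.5-fold changes, 94.7% of 2-fold changes and 98.8% of 4-fold changes. Of its calls 25.8% were false there, and among calls of at least 2-fold 0.513%. The median of the unchanged miRNAs shifted by up to 0.298 on the log2 scale, as changed miRNAs can move the scaling percentile. Whether this shift accounts for all of the false calls was not tested. For the difference of differences the shift reached 0.425, with 10.1% of the calls false. For SW620 against RKO it found 79.9% of 2-fold changes. With no change simulated it called 0 miRNAs, 0 concordant miRNAs and 0 lists. The simulated miRNAs varied independently of each other, and no array was made to stand apart. The 0 lists thus do not show how the list test behaves when members of a list vary together. Because of the false calls, counts with a minimum fold of 2 are given beside those of the contrasts.

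Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots. The total signal per miRNA in the scanner files was not used as the main value, because for 64 to 120 miRNAs per array, of which only some probes were detected, it is higher than the sum of the detected probes. In 22 to 45 of these per array the excess equals the value of another miRNA within 0.2%. Whether the column is faulty is open, so turns of direction seen with it alone are in doubt. No coordinates are given.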

Results

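The data are 12 arrays of exosomal miRNAs, 3 from each of SW620, RKO, HT29 and SW480. Between 347 and 567 of the 2549 human miRNAs were detected on 11 of the arrays and fewer on RKO replicate 3, whose negative controls had a signal of 129 against 64.4 to 67.9 on the other SW620 and RKO arrays. Altogether 144 miRNAs were detected on every array and 1825 on none. The brightest were miR-7975, miR-7977, miR-21-5p, miR-5100 and miR-29a-3p. Together miR-7975 and miR-7977 made up 66.9% to 74.4% of the total signal on the SW620, RKO and SW480 arrays and 40.8% to 47.5% on the HT29 arrays. The oncogenic miR-21-5p had log2 signals of 4.82 in SW620, 4.79 in RKO, 4.66 in SW480 and 2.91 in HT29.

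The title of the series names miR-181a-5p, and the first question is how its exosomal level differs between the lines. It was detected on all 12 arrays and was 12.3-fold to 22.5-fold higher in SW620 and RKO than in HT29 and SW480. Its log2 signal was -0.12 ± 0.091 (SD, n = 3) in SW620, 0.11 ± 0.063 in RKO, -4.38 ± 0.17 in HT29 and -3.74 ± 0.0064 in SW480. The class difference was 4.06 on the log2 scale (SE 0.062, adjusted p = 1.58e-11), with all 6 arrays of the highly metastatic lines above all 6 of the weakly metastatic lines. Its partner from the same hairpin, miR-181a-3p, was not detected on any HT29 or SW480 array and was at least 39.4-fold higher in SW620 and at least 40.6-fold higher in RKO. SW620 and RKO differed in miR-181a-5p by -0.23 (adjusted p = 0.329), while HT29 lay 1.57-fold under SW480 (-0.65, adjusted p = 7.19e-05), a difference that turned to 2.29 with the total signal per miRNA (adjusted p = 0.064). That column is in doubt for miRNAs with only some probes detected: on HT29 replicates 1 and 3 it gave 95.6 and 295, where the detected probes sum to 3.66 and 9.16. Without RKO replicate 3 the fold was 34.0 instead of 22.5 for RKO over HT29 and 26.3 instead of 19.2 for SW620 over HT29. Against SW480 it fell, to 12.3 instead of 14.4 in RKO and to 9.51 instead of 12.3 in SW620. These changes widen the gap between HT29 and SW480. The size of that gap thus rests on the scaling, in which RKO replicate 3 takes part. On slide 1 alone SW620 and RKO exceeded HT29 21.0-fold, against 20.8-fold over all arrays. With the slide as a block the class difference was 4.08 (SE 0.106), a value that rests on HT29 for the slide term. Over the scalings, backgrounds and summaries tried the class difference ran from 2.42 to 5.20.

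**Figure D1:**
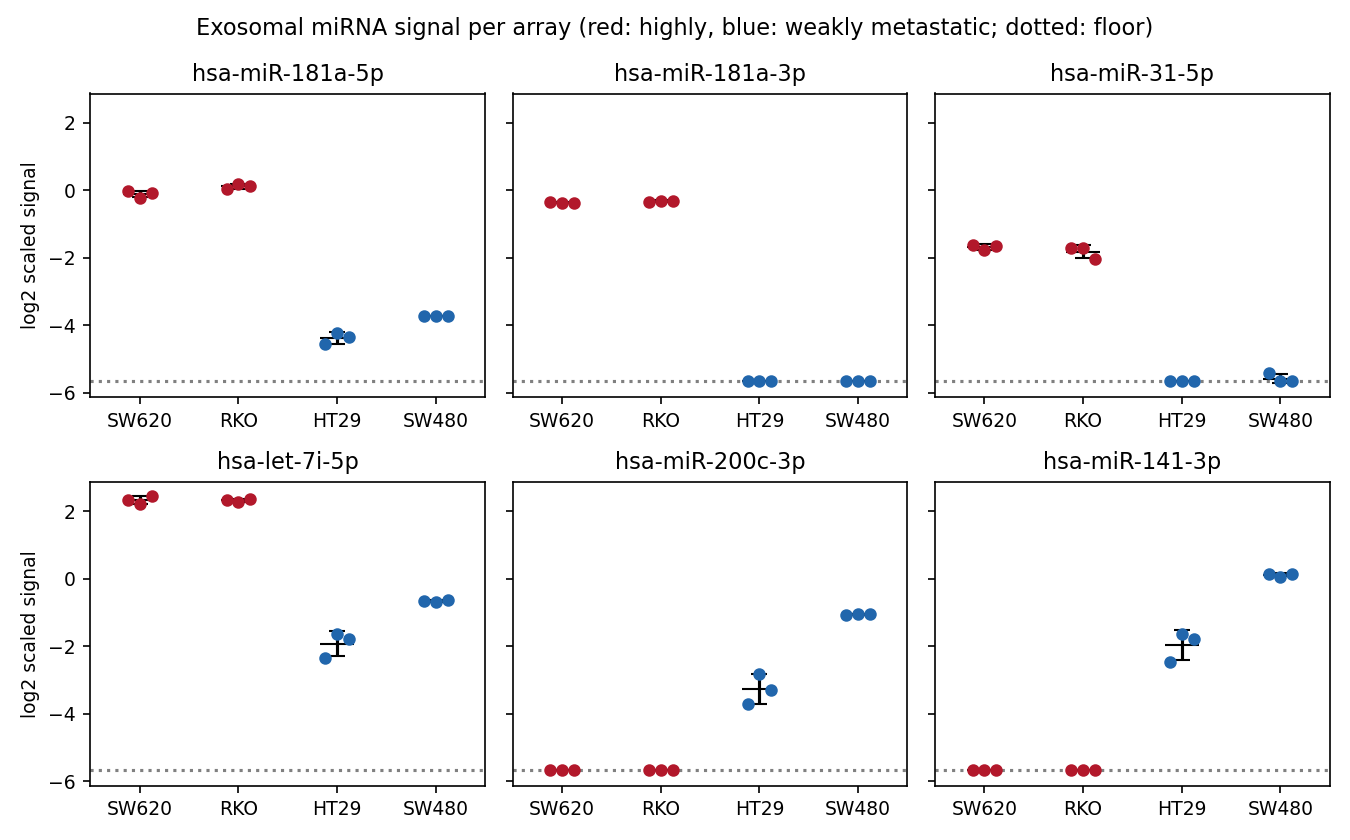
Log2 scaled signal of 6 miRNAs on each array, by cell line. Points are arrays, horizontal bars with whiskers are the mean and SD of 3 arrays, and the dotted line is the floor at -5.67; miR-181a-5p lies near 0 in SW620 and RKO and near -4 in HT29 and SW480, and miR-200c-3p and miR-141-3p lie at the floor in SW620 and RKO.

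The main comparison asks which exosomal miRNAs separate the highly from the weakly metastatic lines. Beside both arms of miR-181a, the oncogenic miR-31-5p, at the floor on all but 1 of the HT29 and SW480 arrays, was at least 13.6-fold higher in SW620 and RKO. Also higher than in both was let-7i-5p, of a family known as tumour suppressors, by 7.91-fold to 19.4-fold. The immune-related miR-155-5p was not detected in HT29 or SW480 and was at least 9.77-fold higher in SW620 and RKO. In the other direction miR-141-3p and miR-200c-3p, which hold epithelial cells in their state by repressing ZEB transcription factors, were not detected on any SW620 or RKO array. In SW620, miR-141-3p was at least 54.9-fold lower than in SW480 and at least 13.0-fold lower than in HT29.

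The other miRNAs highest in SW620 and RKO were miR-18a-5p, miR-151a-5p, miR-151a-3p, miR-301a-3p, miR-126-3p, miR-221-3p and miR-324-5p. With the total signal per miRNA miR-221-3p turned to -1.20 in RKO against HT29 and to -1.02 in SW620 against HT29 (adjusted p = 0.34 and 0.43), and its class difference no longer passed; with the sum of the detected probes it was 3.76. Their class differences ran from 2.94 for miR-151a-3p (SE 0.060, adjusted p = 8.46e-11) to 4.11 for miR-151a-5p (SE 0.054, adjusted p = 5.71e-12). Like miR-181a, miR-151a thus carried both of its arms higher. The other miRNAs lowest in SW620 and RKO were miR-8089, miR-424-5p, miR-150-3p, miR-146a-5p, miR-10a-5p, miR-4430, miR-3934-5p, miR-4252, miR-6792-5p and miR-1290. Of these, miR-10a-5p, encoded among the HOX genes, was 19.9-fold lower in SW620 and 20.6-fold lower in RKO than in SW480, and 3.83-fold and 3.97-fold lower than in HT29. The inflammation-linked miR-146a-5p was not detected in SW620 or RKO and was at least 12.7-fold lower in each of them than in SW480.

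**Figure D2:**
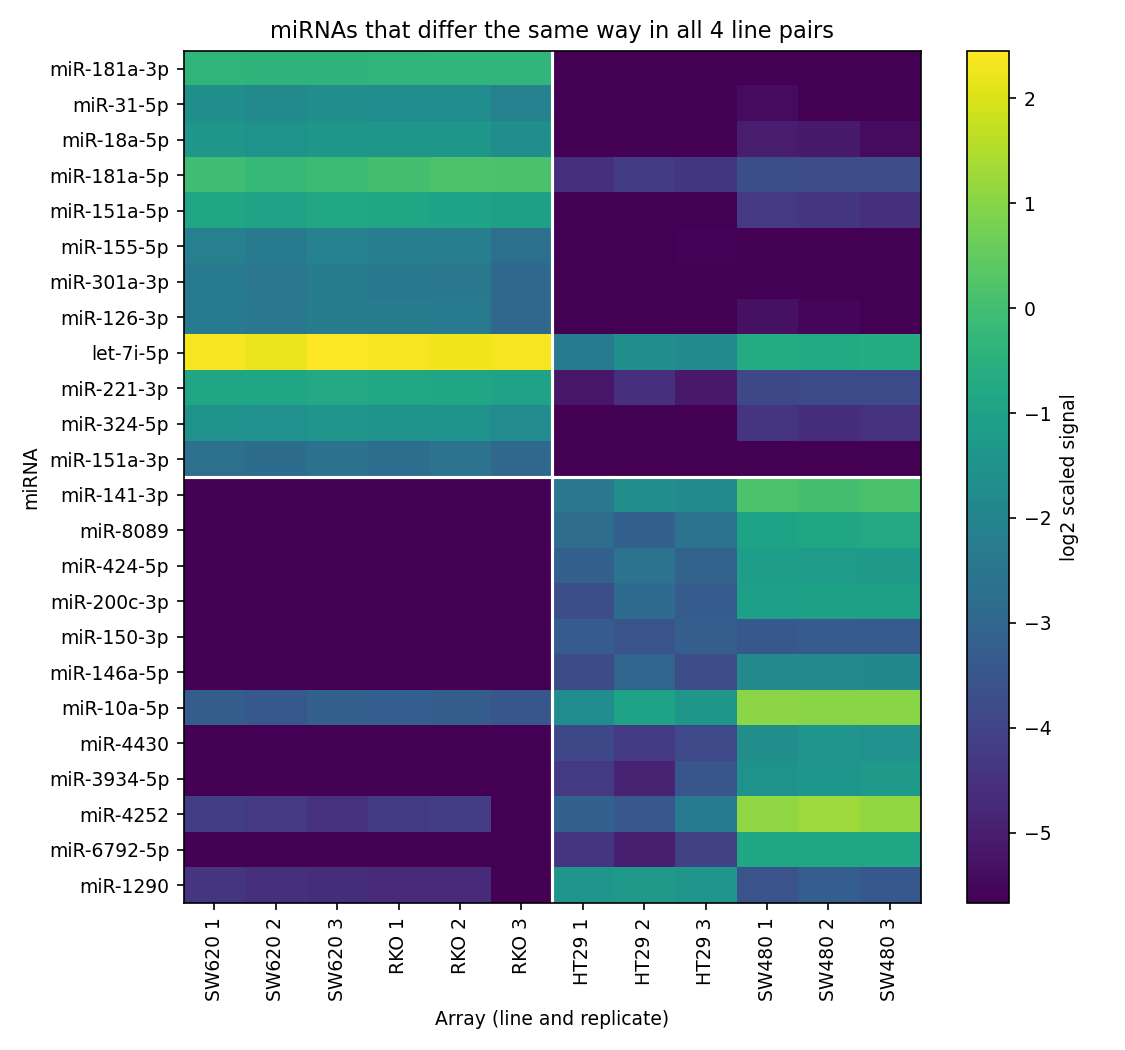
Log2 scaled signal on each of the 12 arrays (columns) of the 12 miRNAs named as higher (upper block) and the 12 named as lower (lower block) in SW620 and RKO than in HT29 and SW480. White lines part the classes and the directions; miR-141-3p and miR-200c-3p are at the floor of -5.67 on all SW620 and RKO arrays.

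Among families, the miR-17-92 cluster and its paralogs, known as drivers of proliferation, was higher as a whole: 12 of 12 tested members rose in the class contrast (12 also when adjusted over the list alone), and 10 were concordant. Examples are miR-17-5p (3.04), miR-20b-5p (2.50) and miR-19a-3p (2.49). The camera test gave an adjusted p of 2.65e-09, and adjusted p = 0.375 with an estimated correlation. In the let-7 family 7 of 9 members rose and let-7b-5p fell, with the same counts adjusted over the list alone (adjusted p = 0.00227, and adjusted p = 0.406 with an estimated correlation). The members let-7i-5p (3.63) and let-7d-5p (2.46) were concordant, whereas let-7f-5p (1.43) and let-7a-5p (1.33) passed against HT29 but not against SW480. All 3 tested members of the miR-221 and miR-222 cluster rose, led by miR-221-3p (3.53), as did all 4 of the miR-29 family, led by miR-29b-3p (1.59). All 4 of the miR-30 family rose too, led by miR-30b-5p (1.19), although miR-30c-5p turned to -0.15 with the total signal per miRNA. In the family of miR-99, miR-100 and miR-125 3 of 4 rose, led by miR-100-5p (2.94), and in that of miR-130 and miR-301 3 of 4, led by miR-301a-3p (3.21). These 5 lists had adjusted p from 0.0098 to 0.0138, the same counts adjusted over the list alone, and each adjusted p = 0.375 with an estimated correlation. The camera test sets a list against the other tested miRNAs. Of all 531 tested, 114 rose and 265 fell, and of the 322 numbered 1000 or higher 207 fell. The calls of the lists in this paragraph thus do not tell a family from miRNAs numbered under 1000 in general. Against SW480 fewer of these lists passed the camera test. The miR-17-92 list passed in SW620 and in RKO, and the miR-221 and miR-222 cluster in RKO (with an estimated correlation adjusted p = 0.713, 0.478 and 0.478). The other lists named here passed in neither. In the camera test miR-30 had adjusted p = 0.811 in SW620 and 0.896 in RKO. The family of miR-99, miR-100 and miR-125 had 0.242 and 0.138, and that of miR-130 and miR-301 0.0725 and 0.0701. Whether the contrasts differ was not tested. With the total signal per miRNA in place of the probe mean, the miR-221 and miR-222 members no longer passed and miR-222-3p turned to -0.98.

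The miR-200 family split by gene cluster. The members miR-141-3p (-4.74) and miR-200c-3p (-3.50), which share a cluster, fell in the class contrast, while miR-429 (1.52), miR-200a-3p (1.25) and miR-200b-3p (0.44), which share another, rose; all 5 passed also when adjusted over the list alone. Without scaling, with the total signal per miRNA and with the slide as a block, 2 of the 3 rises passed. The rise of miR-200b-3p was not seen against SW480 (-0.37 in SW620, adjusted p = 0.15, and -0.46 in RKO, adjusted p = 0.0755, which passed as lower when adjusted over the list alone), and miR-200a-3p turned to -0.34 in SW620 against HT29 with the total signal per miRNA. The list had no call in the camera test (adjusted p = 0.625), with a median of 0.44 and a mean of -1.01, while fry, which tests another question, called it lower (adjusted p = 3.46e-05). The miR-181 family was chosen by the study on these samples, so its call is not independent evidence of its direction. In it 3 of 4 rose and 1 fell, also adjusted over the list alone. The members miR-181a-5p (4.06) and miR-181c-5p (1.11) were concordant, miR-181d-5p rose by 0.59, and miR-181b-5p, detected in SW480 alone, had -0.17, which turned to 0.02 with another background correction. The list's adjusted p of 0.0499 became adjusted p = 0.375 with an estimated correlation.

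Several families moved both ways. In the miR-15/16 family miR-424-5p (-3.61), miR-195-5p (-1.46) and miR-503-5p (-0.92) fell and miR-15b-5p (0.98) and miR-16-5p rose, of 6 tested. In the miR-23/27/24 clusters miR-27b-3p (-2.16) and miR-23b-3p (-1.56) fell and miR-24-3p (1.08) and miR-23a-3p (0.55) rose, of 5. Of 4 HOX cluster miRNAs miR-10a-5p (-3.15) fell, and miR-196b-5p (0.91) and miR-10b-5p (0.53) rose, the latter turning to -0.34 with the total signal per miRNA. The list of miRNAs raised in colorectal tumours had 3 of 6 higher, miR-31-5p (3.87), miR-203a-3p (1.30) and miR-21-5p (1.02), and 3 lower, with miR-135b-5p (-1.28) first. In the family of miR-148 and miR-152 1 of 3 rose, miR-148b-3p (0.97), and in the miR-320 family 1 of 5 fell, miR-320c (-1.52). None of these lists passed the camera test. The miRNAs numbered 1000 or higher, many of them GC-rich, were lower as a group, with 207 of 322 lower and 25 higher (adjusted p = 6.65e-12, and adjusted p = 0.375 with an estimated correlation). Against SW480 the group did not pass, with 49 higher and 34 lower in SW620 (adjusted p = 0.441) and 27 and 50 in RKO (0.137). Scaled by the percentile over all human miRNAs on 11 arrays, 57 were higher and 58 lower in the class contrast, and of the bright list below 4 were higher and 2 lower. A list of bright GC-rich miRNAs had 17 of 21 lower and 0 higher (adjusted p = 0.0399, and adjusted p = 0.736 with an estimated correlation). Both lists gave the same class counts adjusted over the list alone. The lower bright miRNAs come from HT29: against SW480, 10 of 21 were higher and 1 lower in SW620, and 4 and 3 in RKO. Of the bright list miR-3665 turned to 0.087 with the total signal per miRNA. On RKO replicate 3, 327 of the 531 tested miRNAs lay at the floor, against 73 to 188 on the other arrays.

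Markers of other cell types were tested in some lists only. No tested miRNA belonged to the lists for stromal cells, striated muscle, hepatocytes or the C19MC cluster of the placenta. Of the endothelial list miR-126-3p rose (3.19), and of 3 tested leukocyte miRNAs miR-155-5p rose (3.40), miR-146a-5p fell (-2.97) and miR-150-5p had 0. Of the erythrocyte and platelet list miR-486-5p fell (-0.55), and of the neural list miR-9-3p fell (-1.36) and miR-128-3p rose (0.21). Of the DLK1-DIO3 cluster 4 of 25 members were tested and 2 fell, miR-134-5p (-0.94) and miR-370-3p (-0.75). All 3 tested members of the miR-371-373 and miR-302 clusters fell, with miR-371a-5p (-0.61) first, while miR-371a-3p and miR-371b-5p turned to 0.04 and 0.01 with another background correction. Of lists with fewer than 3 tested members, miR-34a-5p, of a family that p53 induces, rose (1.35), as did miR-183-5p (2.03) and miR-96-5p (0.89), while the intestinal miR-192-5p fell (-0.88). Scaled by the percentile over all human miRNAs on 11 arrays, miR-371a-5p turned to 0.49, miR-192-5p to 0.03 and let-7b-5p to 0.46.

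In total 379 of 531 miRNAs passed the class contrast, 114 higher and 265 lower, of which 213 differed at least 2-fold. The excess of lower miRNAs depends on the processing: among the 144 miRNAs detected on all 12 arrays 64 were higher and 53 lower, and scaled by the percentile over all human miRNAs on 11 arrays 162 were higher and 82 lower. Of the 531 tested miRNAs 91 were concordant in all 4 pairs of lines, 60 higher and 31 lower, 54 of them at least 2-fold in each pair. The counts were 66 higher and 52 lower without RKO replicate 3, and scaled by the percentile over all human miRNAs on 11 arrays 49 and 4. Independent lists of these lengths would share 0.974 higher and 3.29 lower miRNAs, and simulated arrays without a change gave 0, but the pairs share lines, to which part of the excess may belong. The pairs SW620 with SW480 and RKO with HT29, which share no arrays, had 68 miRNAs higher in both against 26.0 for independent lists, and 32 lower in both against 37.7. The pairs RKO with SW480 and SW620 with HT29 had 61 higher in both against 19.9, and 44 lower in both against 46.4. Because the SW620 and RKO arrays were alike, these pairs are not independent either. A level common to SW620 and RKO can put a miRNA in both lists, so the excess cannot be read against independent lists. The miRNAs that passed the class contrast without being concordant were led by miR-185-5p (adjusted p = 0.00216), let-7f-5p and let-7a-5p among the higher and by miR-6769b-5p (-3.11), miR-1229-5p (-2.46) and miR-4800-5p (-2.44) among the lower, the last 3 of which were high in HT29. Other ways to split the lines into pairs gave 367 and 345, and with the cell line as a random block 41 miRNAs passed. With the slide as a block, where HT29 alone sets the slide term, 286 passed, 162 of them at least 2-fold. Within slide 1 SW620 and RKO against HT29 gave 357 (299 at least 2-fold), and over all arrays 392 (317).

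SW620 against SW480 compares a highly with a weakly metastatic line. In SW620, miR-181a-3p was at least 39.4-fold higher, miR-31-5p at least 14.9-fold, miR-18a-5p 13.8-fold, miR-181a-5p 12.3-fold, and miR-151a-5p was next. Lower were miR-141-3p, by at least 54.9-fold, miR-4252 by 45.2-fold, miR-8089 by at least 27.9-fold, miR-6792-5p by at least 27.3-fold and miR-200c-3p by at least 24.4-fold. The miR-15/16 family, known to restrain the cell cycle, fell in 5 of 6 members (5 adjusted over the list alone; adjusted p = 0.00015, and adjusted p = 0.503 with an estimated correlation). Its members miR-195-5p (-2.92) and miR-503-5p (-1.84) were detected in SW480 alone of the 4 lines. The miR-17-92 list had 10 of 12 members higher and 1 lower, and 11 and 1 adjusted over the list alone (adjusted p = 0.00015, and adjusted p = 0.713 with an estimated correlation). In all 195 miRNAs passed, 122 higher and 73 lower, 117 of them at least 2-fold. The lines share no slide, and without RKO replicate 3, which takes part in the scaling, 111 were higher and 140 lower.

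RKO against HT29 compares the other pair of classes named in the same order. In RKO, miR-181a-3p was at least 40.6-fold higher, miR-151a-5p at least 26.0-fold, miR-181a-5p 22.5-fold, miR-7-5p 21.8-fold and let-7i-5p 19.1-fold. Lower were miR-663a by 50.5-fold, miR-6769b-5p by at least 48.3-fold, miR-7150 by 48.2-fold, miR-1229-5p by 28.3-fold and miR-7847-3p by at least 23.7-fold. All 12 tested members of the miR-17-92 list rose (12 adjusted over the list alone; adjusted p = 3.04e-09, and adjusted p = 0.296 with an estimated correlation), and 8 of 9 let-7 members, 9 of 9 adjusted over the list alone. The miRNAs numbered 1000 or higher fell in 224 of 322 cases and rose in 16, but in 74 and 56 with the percentile over all human miRNAs on 11 arrays. In all 387 miRNAs passed, 113 higher and 274 lower, 328 of them at least 2-fold. More were higher when scaled by that percentile (173 against 92 lower) and among the miRNAs detected on all 12 arrays (68 against 60). Without RKO replicate 3, where many miRNAs lay at the floor and which takes part in the scaling, the split was 176 higher and 224 lower. The differences of the lower miRNAs named became smaller. On the log2 scale they were -4.59 instead of -5.66 for miR-663a, -5.11 instead of -5.73 for miR-6769b-5p and -4.28 instead of -5.59 for miR-7150. For miR-1229-5p it was -3.77 instead of -4.82, and for miR-7847-3p -4.21 instead of -4.70. Those of the higher miRNAs named became larger, such as 5.09 instead of 4.49 for miR-181a-5p and 4.83 instead of 4.25 for let-7i-5p. Part of these changes comes with the scaling. SW620 against HT29 holds no RKO array, yet miR-181a-5p, let-7i-5p, miR-6769b-5p, miR-7150 and miR-663a each shifted 1.37-fold there. On RKO replicate 3 miR-181a-5p lay at 0.11, as did the mean of RKO, so its value there does not account for its change.

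The remaining pairs repeat these lines. In RKO against SW480 miR-181a-3p was at least 40.6-fold, miR-181a-5p 14.4-fold, miR-31-5p at least 13.6-fold, miR-18a-5p 13.4-fold and miR-151a-5p 10.9-fold higher. Lower were miR-4252 by 58.8-fold (49.4-fold without RKO replicate 3), miR-141-3p, miR-8089 by at least 25.4-fold, miR-6792-5p by at least 24.9-fold and miR-200c-3p by at least 22.2-fold. In SW620 against HT29 miR-181a-3p was at least 39.4-fold, miR-151a-5p at least 27.4-fold, miR-7-5p 23.5-fold, let-7i-5p 19.4-fold and miR-181a-5p 19.2-fold higher. Lower were miR-6769b-5p by 37.6-fold, miR-7847-3p by at least 26.0-fold, miR-7150 by 22.8-fold, miR-4298 by at least 21.7-fold and miR-663a by 21.0-fold. Without RKO replicate 3, which takes part in the scaling, these folds were 27.5, 18.6, 16.7, 15.7 and 15.3, while those of let-7i-5p and miR-181a-5p rose to 26.5 and 26.3. RKO against SW480 gave 183 miRNAs, 86 higher and 97 lower, and 112 at least 2-fold. These lines share no slide. The split was 109 and 57 with another background correction. With the slide as a block it was 103 and 46, but HT29 alone sets the slide term. SW620 against HT29 gave 377, 123 higher and 254 lower, and 310 at least 2-fold. Scaled by the percentile over all human miRNAs on 11 arrays more were higher in both, 54 against 31 lower and 189 against 89. Among the miRNAs detected on all 12 arrays they were 53 against 42 and 69 against 54.

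SW620 against RKO asks how far lines of the same class differ. Only miR-3648 (0.56, SE 0.090) and miR-595 (0.53, SE 0.085) passed in limma, both 1.45-fold to 1.48-fold higher in SW620 with signals at or near the floor and an adjusted p of 0.0332; 61 miRNAs had an unadjusted p under 0.05. No miRNA differed at least 2-fold past the threshold, and without RKO replicate 3 none passed; with another background correction both turned to -0.01 and -0.09. The miR-17-92, let-7, miR-181 and miR-200 lists each had 0 members past the threshold. The list of bright GC-rich miRNAs was higher in SW620 in the camera test (adjusted p = 1.29e-07, and adjusted p = 0.937 with an estimated correlation), with 0 of 21 members past the threshold and 6 adjusted over the list alone. Over the 144 miRNAs detected on every array, the median absolute difference between a SW620 and a RKO array was 0.105 on the log2 scale. It was 0.134 between SW620 arrays, 0.243 between RKO arrays, 0.287 between HT29 arrays and 0.0574 between SW480 arrays.

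**Figure D3:**
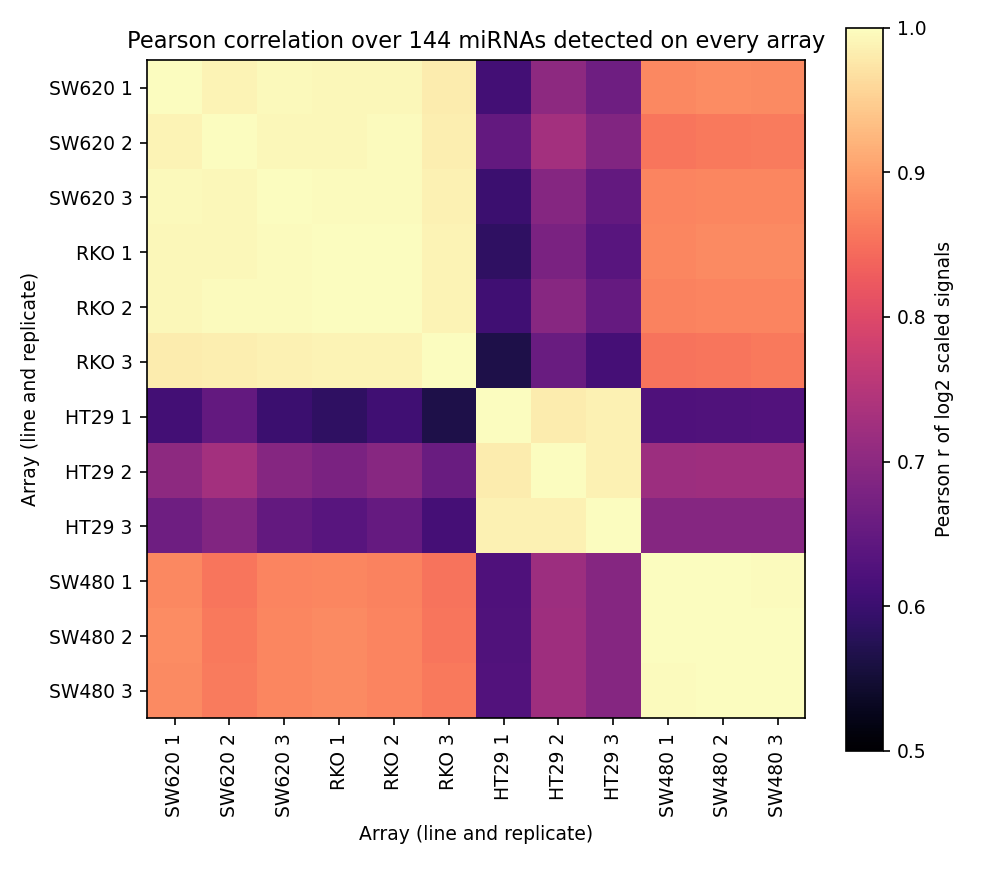
Pearson correlation of log2 scaled signals over the 144 miRNAs detected on every array, for each pair of the 12 arrays; both axes list the arrays by line and replicate. SW620 and RKO arrays correlate with each other between 0.981 and 0.998, with SW480 between 0.854 and 0.879, and HT29 correlates with SW480 between 0.625 and 0.721.

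HT29 against SW480 compares the lines labelled weakly metastatic. Array signals were far higher in HT29 for miR-7150 (83.3-fold), miR-663a (83.2-fold), miR-630 (at least 76.8-fold), miR-5787 (52.8-fold) and miR-5703 (at least 51.0-fold). Signals were lower for miR-4252 (17.8-fold), miR-1183 (at least 12.6-fold), miR-6792-5p (12.1-fold), miR-7-5p (9.30-fold) and miR-3944-5p (9.12-fold), although miR-7-5p turned to 0.96 with the total signal per miRNA (adjusted p = 0.000655). Whether the content of the exosomes differs as much was not tested. Without RKO replicate 3, which takes part in the scaling, the folds were 47.2 for miR-7150, 47.1 for miR-663a, 54.7 for miR-630, 29.9 for miR-5787 and 36.3 for miR-5703. They were 31.4 for miR-4252, 21.4 for miR-6792-5p and 16.1 for miR-3944-5p. The following families were lower in HT29: all 5 of the miR-200 family (adjusted p = 0.00263), 10 of 12 of the miR-17-92 list (4.15e-05), 8 of 9 of let-7 (0.000371), all 6 of the miR-15/16 family (0.000145), all 5 of the miR-23/27/24 clusters (0.00364), all 4 of the miR-30 family (0.00871) and all 4 HOX cluster miRNAs (0.00553). Each of these lists had the same counts adjusted over the list alone and adjusted p = 0.341 with an estimated correlation. With the total signal per miRNA, miR-17-5p turned to 1.34 and miR-200a-3p to 1.19, and the miR-30 and HOX lists kept 1 lower member each. The miRNAs numbered 1000 or higher were higher in 218 of 322 cases (220 adjusted over the list alone) and lower in 32 (adjusted p = 1.27e-16, and adjusted p = 0.341 with an estimated correlation), and bright GC-rich miRNAs in 20 of 21 (adjusted p = 0.000295, and adjusted p = 0.408 with an estimated correlation). In all 384 miRNAs passed, 259 of them higher, and 320 at least 2-fold. Among those detected on all 12 arrays 55 were higher and 72 lower. Slide 2 holds only 1 HT29 array, so the spread of HT29 is missing there and no count is given. The miR-181a-5p difference on slide 2 alone was -0.62, against -0.65 over all arrays, both in the scaling that includes RKO replicate 3. Of 405 that passed without RKO replicate 3, 211 were higher, and scaled by the percentile over all human miRNAs on 11 arrays 101 were higher and 158 lower, with 86 and 48 among those numbered 1000 or higher and 6 and 1 in the bright list; the families named above stayed lower.

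**Figure D4:**
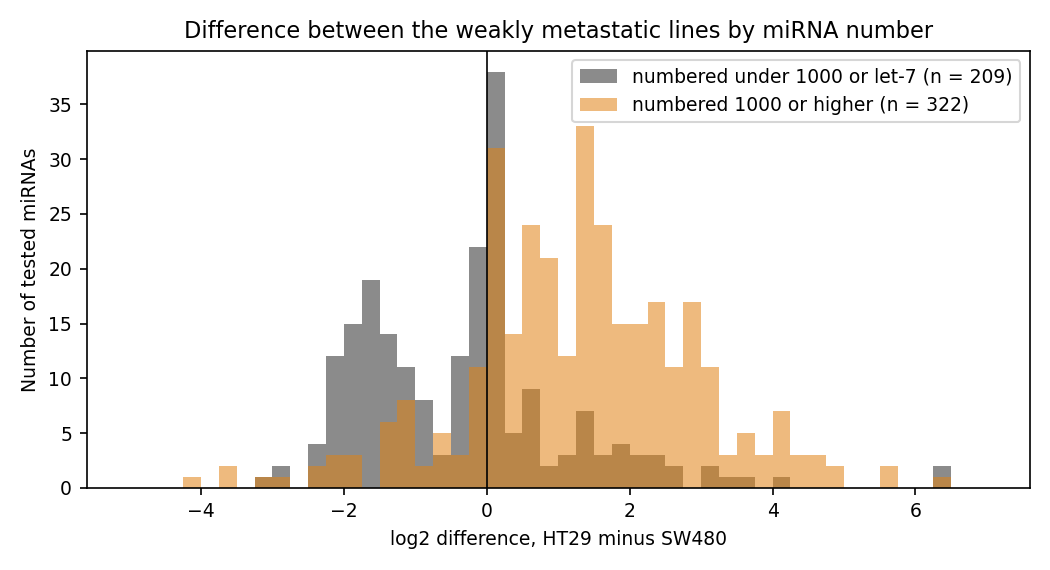
Histogram of the log2 difference between HT29 and SW480 for the 531 tested miRNAs (number of miRNAs on the vertical axis), for the 322 numbered 1000 or higher (orange) and the rest (grey). Of the 322, 218 were higher in HT29 and 32 lower past the threshold.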

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

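The tests of arrays on the same slide, of less RNA on an array and of whole lines exchanged were chosen after the results were seen. Of 56 groups of 6 arrays tested for a value far from the rest, 15 had one, where chance gives about 1 in 20 groups.

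RKO replicate 3 stood apart from the other SW620 and RKO arrays in 12 of the groups with such a value. On it 7.14% of the human miRNAs were detected (others 14.2% to 17.3%), a negative control signal of 129 (others 64.4 to 67.9) and a median processed signal of -25.5 (others -3.10 to -1.29). Less RNA on the array is excluded as the whole cause, since with the miRNAs ranked in 3 groups of 119 by signal, the unscaled signal of the brightest group was 0.944 times that on the other RKO arrays. A raised background may be the cause. The dimmest group fell by 0.68 on the log2 scale and the middle group by 1.27, and 8 of 119 in the dimmest group were detected. The floor limits how far dim miRNAs can fall, so the test set for this cause leaves it open. Unscaled and without the floor, the median ratio to the other RKO arrays was -0.32 in the dimmest group and 0.28 in the middle group. Without this array the class count was 380 instead of 379, with 136 higher and 244 lower.

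The miRNAs that stood low on this array were miR-31-5p at -2.05, miR-155-5p at -2.67, miR-301a-3p at -2.93 and miR-126-3p at -2.91 on the log2 scale. On it miR-4252 lay at -5.67, miR-1290 at -5.67, miR-185-5p at -5.67, miR-1229-5p at -5.67 and miR-4800-5p at -5.67, which is the floor. Among the weakly metastatic lines SW480 replicate 1 had miR-31-5p at -5.42 and miR-126-3p at -5.30, and HT29 replicate 3 had miR-155-5p at -5.58, each just above arrays at or near the floor.

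The SW620 minus SW480 and RKO minus HT29 differences were not alike: 367 miRNAs differed between them, 321 of them at least 2-fold. The most that any of 99 other assignments of the 12 arrays to 4 groups gave was 293 (1 of 100), which excludes only that single arrays were grouped at random. The largest were miR-663a (7.65), miR-7150 (7.46), miR-630 (6.67), miR-5703 (6.48) and miR-5787 (6.06), and in the other direction miR-4252 (-3.77), miR-1183 (-3.66), miR-6792-5p (-3.60), miR-3944-5p (-3.19) and miR-7-5p (-3.11). Without RKO replicate 3 they were 6.20, 5.78, 5.79, 5.11 and 4.93, and -5.21, -4.16, -4.42, -4.01 and -3.79. Since SW620 and RKO are alike, these are mostly differences of HT29 from SW480, and of the 278 miRNAs detected on all HT29 and SW480 arrays the 169 numbered 1000 or higher lie 2.16 (bootstrap SD 0.293) above the other 109 in that comparison. Signals near the background are excluded as the whole cause, as the gap among the brighter of these miRNAs, those above the median signal, was 2.75. The GC content of the probes may be part of it: with the GC trend of each array removed 30.1% of the gap was left, between the bounds set for and against, and GC content goes with the number, so the explanations cannot be told apart; a difference between the exosomes of the lines was not tested.

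The SW620 and RKO arrays resembled each other as closely as the arrays within SW620 or within RKO do, though less closely than those within SW480. Arrays of the same slide resembling each other is excluded as the whole cause, because the HT29 arrays of slide 1 lay 14.4 times as far from them as they lay from each other. A single source of RNA behind both labels lay within the bound set for it: without RKO replicate 3, 4.44% of the miRNAs had an unadjusted p under 0.05 between SW620 and RKO. With that array 61 of 531 had one. The share is not a clean measure of noise. On each SW620 array and on RKO replicates 1 and 2, 157 to 175 of the tested miRNAs lay at the floor. A miRNA at the floor in both lines cannot differ between them. Exosomes that are alike in both lines would give a low share too, and nothing in the tables decides between these. If the source may be 1, the 4 pairs behind the concordant miRNAs would hold only 2 separate comparisons.

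Chance was also tested by other splits of the arrays. For each pair of lines only 10 splits of its 6 arrays exist, too few for a share under 0.05; in fits over all 12 arrays the real counts were 195 for SW620 and SW480, 387 for RKO and HT29, 183 for RKO and SW480, 377 for SW620 and HT29, 2 for SW620 and RKO and 384 for HT29 and SW480, each reached by 1 of 10 splits, and the highest others were 0, or 5 for RKO and HT29. With 1 mean per class 129 miRNAs passed between the classes, and the highest of the 99 other splits drawn gave 19 (1 of 100). These splits part the arrays of a line, so they exclude only a random grouping of single arrays and say nothing of the classes. Whole lines allow 3 splits, too few, with 379 for the real one and 367 for the highest other (1 of 3). For the 91 concordant miRNAs the highest other was 0 (1 of 100), with the same restriction; the pairs that share no arrays had 32 and 44 miRNAs lower in both, against 37.7 and 46.4 for independent lists, so the lower ones show no excess there. For the 10 lists called between the classes 34 of 100 assignments gave as many, with up to 14, so chance is not excluded for the number of lists.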

How the results depend on the processing

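The sum of the detected probes' total signals, the fits within a slide and the percentile on 11 arrays were chosen after seeing the data; the other alternatives were planned. In miR-181a-5p the class difference passed under each alternative, from 2.42 to 5.20. Of 817 class differences of the 29 other miRNAs named for the classes 802 kept their side of the threshold, 15 weakened and 0 reversed. Outside the class models 4 of 759 weakened, so most of the weakening came with those models. These miRNAs were named for their large differences on the same arrays, so their stability is not independent evidence. Within pairs some miRNAs reversed past the threshold. With the total gene signal these were miR-17-5p (1.34), miR-221-3p (2.56) and miR-7-5p (0.96) in HT29 against SW480 and miR-196a-5p in RKO (-1.71) and SW620 (-1.14) against HT29; that column is in doubt, and the sum of detected probes turned none of them. With quantile normalization and that percentile it was miR-371b-5p in HT29 against SW480 (-0.37, -0.50), and with the latter miR-494-3p in SW620 against HT29 (1.02).

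With the percentile over all human miRNAs on 11 arrays, where it lies near the background, counts (higher/lower) were class 244 (162/82), SW620 against SW480 112, RKO against SW480 85 (54/31), SW620 against RKO 0, difference of differences and 1 line split 207 (82 higher), the other split 184 (117/67), concordant 53 (49/4) and lists 3 (2/1). RKO against HT29 was 173/92, SW620 against HT29 189/89 and HT29 against SW480 101/158, so the majority direction rests on the scaling.

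The count for SW620 against RKO, 2, was 0 with quantile normalization, no scaling, normexp background, log2 probe means, either other floor, no detection filter, miRNAs detected on all 12 arrays, the replicate block, the slide block, a 2-fold minimum, only the 6 arrays and slide 1 alone; it was 1 with the total gene signal, trend and robust eBayes or the sum of detected probes, 6 with the authors' table, and 0 to 5 with an array left out. With the replicate block the class count was 377.

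With the total gene signal SW620 against SW480 gave 73 higher and 52 lower (1.2e+02 in all) and RKO against SW480 113, concordant miRNAs were 51 and lists 6. Without a detection filter RKO against SW480 gave 120. With only the 144 miRNAs detected on all 12 arrays, counts were class 117, SW620 against SW480 88, RKO against HT29 128, RKO against SW480 95, SW620 against HT29 123, HT29 against SW480 127, difference of differences 126, other line splits 126 and 122, concordant 39 and lists 3. Class models gave 41 with the line as a random block and 129 with 1 mean per class. The 2-fold minimum, by its construction, gave class 213, SW620 against SW480 117, RKO against SW480 112, other line splits 162 and 135, and concordant 54. The lists called were 0 with an estimated correlation and 18 with fry, instead of 10.

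The share of higher among the called miRNAs shifted by over 10 percentage points in some. With quantile normalization it was 108/99 for SW620 against SW480, 211/177 for HT29 against SW480, 208/148 for the difference of differences and 208/148 and 161/173 for the other line splits. With normexp it was 130/186 for RKO against HT29, 109/57 for RKO against SW480 and 63/15 for concordant miRNAs. On miRNAs detected on all 12 arrays it was 64/53 for the classes, 68/60 for RKO against HT29, 69/54 for SW620 against HT29, 55/72 for HT29 against SW480, 54/72 for the difference of differences, 54/72 and 74/48 for the other splits, 31/8 for concordant miRNAs and 1/2 for lists. With the authors' table it was 142/197 for the classes, 167/217 for RKO against HT29, 161/193 for SW620 against HT29, 4/2 for SW620 against RKO, 187 lower of 368 for HT29 against SW480, 170/167 for the difference of differences and 170/167 and 159/155 for the other splits. With the slide block, where HT29 alone sets the slide term, it was 130/39 for SW620 and 103/46 for RKO against SW480. Without RKO replicate 3 it was 111/140 for SW620 against SW480, 176/224 for RKO against HT29, 211 higher of 405 for HT29 against SW480, 192/180 for the difference of differences, 192/180 and 156/183 for the other splits and 66/52 for concordant miRNAs. Class models gave 30/11 and 75/54, the 2-fold minimum 141/21 for a line split, fry 10/8, lists without a filter 8/4, and SW620 against RKO with the total gene signal 0/1. The median of all tested class differences was -0.38, and 0.25 with that percentile, -0.16 with quantile normalization, -0.03 with normexp, 0.06 for miRNAs detected on all 12 arrays and -0.15 without RKO replicate 3, so counts of higher and lower are relative to it.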

Other observations

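The miRNAs whose arms both passed between the classes moved mostly together. Besides miR-181a and miR-151a, the arms miR-31-5p (3.87) and miR-31-3p (3.19), miR-455-3p (2.81) and miR-455-5p (1.22), miR-140-5p (1.94) and miR-140-3p (1.46), and miR-574-5p (2.01) and miR-574-3p (1.01) were higher in SW620 and RKO. Both arms of miR-4485 were lower (-1.23 and -1.27).

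That arms of 1 hairpin change together was written as a test before its result was seen. Of 37 hairpins with both arms tested 21 had the same sign, 56.8%, while random pairings of the same arms gave a median of 45.9% and 59.5% at the upper bound (one-sided permutation p = 0.083, 10000 pairings). The result lies between the bounds set for and against, so the test does not decide. Of 14 hairpins with both arms past the threshold 12 had the same direction, a count that could come from the choice of arms and was not tested (56.8% over all 37).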
